A study of Mus musculus with 16 samples.

How the data were processed

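RNA from sorted spermatogenic cells of 8-week-old C57BL/6J male mice was sequenced as polyA-enriched bulk libraries. There were 16 libraries in 8 groups of 2, from 4 cell types (spermatogonia, MI spermatocytes, MII spermatocytes and spermatids) and 2 genotypes (wild type and Tex10-deficient, a floxed and a null Tex10 allele with the Stra8-iCre recombinase). How the cells were sorted is not given in the sources used here. Per the submitters' processing notes, the authors used FastQC 0.10.1, Trim Galore 0.6.3, cutadapt, STAR 2.7.6a and Cufflinks 2.2.1 with the mouse build mm10. The gene annotation, the filter that left 13101 genes in the table and any further scaling between libraries are not given in the sources used here.

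The deposited values were FPKM (fragments scaled by transcript length and by the mapped fragments of the library) to which the authors had added 1. The smallest value was 1, and the number of decimals changed at 11 and at 101, that is 1 above 10 and 1 above 100, as it does when 1 is added to values of a fixed number of digits. The added 1 was subtracted, so that levels are given as FPKM. Of the values, 3.33% were then 0, and a gene is described as listed at 0 because a failed estimate can also give a 0. For 1 gene, 1110002L01Rik, the cell of 1 library held a letter, and the gene was left out. Read numbers are unknown because only FPKM were used, so no counting intervals are given. FPKM totals per library ran from 187713 to 533859 and are not a depth.

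Groups were taken from the sample titles. For 6 of the 8 Tex10-deficient libraries the cell type field of the labels names another cell type than the title does, whereas titles and fields name the same type for the 8 wild-type libraries. By correlation across genes, 8 of 8 Tex10-deficient libraries were nearest to a wild-type library of the type in the title and 2 of 8 to one of the type in the field. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Gene positions are from GENCODE M21 (GRCm38, the assembly that mm10 names), matched by symbol for 12593 genes, with a further 481 given a chromosome from RefSeq symbols.

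Genes with at least 1 FPKM in at least 2 libraries were tested (13099 genes). Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), in a single fit of the 8 groups with 8 residual degrees of freedom. Fold changes on this scale understate the change of genes with low levels. Contrasts were Tex10-deficient minus wild type in each cell type, their average over the 4 cell types, an F test of whether they differ between cell types, and successive cell types within the wild type. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of 25 gene lists, 22 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The erythroid and mitochondria-encoded lists had 0 genes in the table and the pluripotency list had 3, so these were not tested.

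Design, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took Tex10 in every library, and in each comparison of genotypes up to 10 rises and 10 falls among called genes. These needed both Tex10-deficient libraries beyond both wild-type libraries, a mean of at least 5 FPKM in the higher group and a symbol that was not a predicted name. Where none passed, the 5 smallest p were taken. The rule added up to 4 members of each list that passed, the 10 smallest p for the average and the F test, and up to 3 of the most abundant members of each marker list. Genes named outside this rule are said to have been chosen after their values were seen.

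The steps were tested on simulated data for the MI spermatocyte comparison with 13099 genes, of which 200 were changed. There 66% of genes changed by a log2 of 2 and 17% of those changed by a log2 of 1 were recovered, with 4 false calls among 87. The simulated noise was independent between genes and libraries, with the same SD in all groups, and changed genes were drawn from higher levels. The real libraries differ in these respects, so the recovery and the share of false calls may not carry over. The alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, eBayes without the trend, array weights, the replicate number as a block shared by both genotypes or centred within each genotype, grouping by the cell type field, only the 4 libraries compared, and each library left out in turn. Fits without the MII libraries, with robust eBayes, with the replicate number within genotype as a random effect (duplicateCorrelation), and of list tests with each library left out were added after seeing the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.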

Results

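Transcripts were measured in sorted spermatogonia, MI spermatocytes, MII spermatocytes and spermatids of wild-type and Tex10-deficient mice, with 2 libraries per group and 16 in all. The Tex10-deficient mice carried a floxed and a null Tex10 allele with Stra8-iCre, a recombinase driven by a promoter active in spermatogonia. The series asked which transcripts change in spermatogenic cells when Tex10 is missing. Between 10044 and 12394 genes per library reached 1 FPKM. Replicate libraries correlated with a Spearman rho across genes from 0.881 in wild-type MII spermatocytes to 0.971 in wild-type spermatids, and genes are not independent replicates. All levels below are mean FPKM ± SD (n = 2 libraries), and log2 changes are limma estimates on log2(FPKM + 1) with Benjamini-Hochberg adjusted p over 13099 genes.

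Tex10 encodes a nuclear protein of a complex that takes part in ribosome maturation. The gene (XLOC_015051) lies on chromosome 4 from 48430858 to 48473459 on the minus strand in mm10. It was lower in all 8 Tex10-deficient libraries than in the wild-type libraries of the same cell type. The wild-type libraries held 55.4 and 50.02 FPKM in spermatogonia, 63.1 and 57.5 in MI spermatocytes, 13.8 and 27.4 in MII spermatocytes, and 98.8 and 116 in spermatids. The Tex10-deficient libraries held 13.6 and 18.96, 10.9 and 14.6, 8.11 and 7.29, and 31.8 and 34.8 FPKM in the same order. Mean levels were 30.9%, 21.1%, 37.4% and 31.0% of wild type. Averaged over cell types, Tex10 fell by 1.68 on the log2 scale (SE 0.15, limma adjusted p = 0.00049). Among single cell types it passed in MI spermatocytes (log2 change −2.17, SE 0.31, adjusted p = 0.012), and the adjusted p was 0.10, 0.095 and 0.23 in spermatogonia, MII spermatocytes and spermatids. The values cover the whole gene and may include exons outside the deleted part, which the labels do not name. Leaving out any 1 of the 4 MI spermatocyte libraries ended the call in that cell type, with adjusted p = 0.11 and 0.18 without wild-type replicates 1 and 2, and 0.15 and 0.10 without Tex10-deficient replicates 1 and 2. Without wild-type MII replicate 1 the MII change was −1.71 with adjusted p = 0.0031. Without wild-type MII replicate 1 or 2 the spermatogonia change of −1.65 passed, with adjusted p = 0.048 in both fits.

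**Figure D1:**
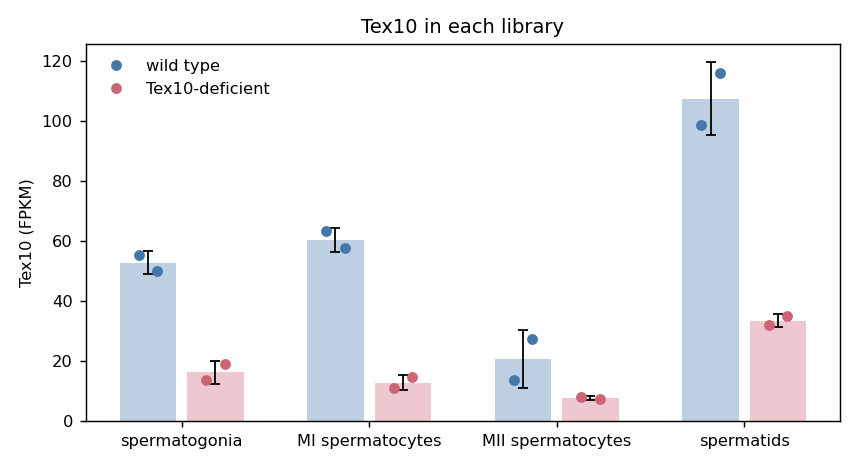
Tex10 level in FPKM in each of the 16 libraries (points), with group means (bars) and SD (error bars, n = 2), by sorted cell type and genotype. The Tex10-deficient libraries sit between 7.29 and 34.8 FPKM, below the wild-type libraries of each cell type.

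Within the wild type, MI spermatocytes held far more transcripts of late spermatocytes and of the sperm tail than spermatogonia did. Ldhc, the germ cell lactate dehydrogenase, stood at 13.7 ± 3.0 FPKM in spermatogonia and 986 ± 161 in MI spermatocytes, and all 28 sperm flagellum genes tested rose (median log2 change 5.11). Dmrt1, a transcription factor of spermatogonia, stood at 54.1 ± 4.5 FPKM in spermatogonia and 7.21 ± 0.41 in MI spermatocytes, and 10 of 15 spermatogonia markers fell. In the same list 2 markers rose, and Dmrtb1 stood at 17.4 ± 2.4 FPKM in spermatogonia and 91.1 ± 1.4 in MI spermatocytes. All 24 X-linked housekeeping genes were lower in MI spermatocytes (median −1.86), of which 22 fell over all genes and 23 adjusted over the list alone. Immune markers fell too, all 13 of them (median −4.21), with Cd74 at 169 ± 46 FPKM in spermatogonia and 1.29 ± 0.50 in MI spermatocytes. Lyz2 stood at 75.6 ± 0.9 and 0.171 ± 0.242 FPKM and C1qb at 67.2 ± 50.6 and 0.268 ± 0.081. These transcripts may come from immune cells in the spermatogonia fraction, which was not tested. Differences between the fractions are thus not all shown to be changes within germ cells. In limma, 6800 genes differed, 3439 higher and 3361 lower, and 15 of 22 lists passed camera, 4 upwards and 11 downwards. None of the 15 held with an estimated correlation, where the adjusted p ran from 0.254 to 0.431, while fry called 18 lists.

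Wild-type MII spermatocytes differed from MI spermatocytes in germ cell and in somatic transcripts. Meiotic prophase markers fell (17 of 22 genes, median −2.55), as did piRNA pathway genes (19 of 20, median −2.69), late spermatocyte markers (14 of 15, median −2.34), sperm flagellum genes (24 of 28, median −2.43) and DNA repair genes (13 of 19, median −1.59). Leydig cell markers rose (8 of 8, median 4.74), and Insl3, a Leydig cell hormone, stood at 7.85 ± 3.90 FPKM in MI and 690 ± 322 in MII spermatocytes. Immune markers rose (13 of 13, median 4.003), as did Sertoli cell markers (7 of 7, median 2.87), immediate early and stress genes (14 of 14, median 4.59) and X-linked housekeeping genes (23 of 24, median 2.03). In limma, 7489 genes differed, 3928 higher and 3561 lower, and 15 lists passed camera, 10 upwards and 5 downwards. Adjusted p with an estimated correlation ran from 0.243 to 0.281 over these lists, so none held, while fry called 19. The 2 wild-type MII libraries differed from each other, with a median late spermatocyte marker level of 4.40 and 6.04 on the log2 scale. Myoid and endothelial markers rose as well (5 of 6, median 3.06). Joint rises of Leydig, immune, Sertoli, and myoid and endothelial markers argue against changes within MII spermatocytes alone, and for somatic RNA in this fraction. How far somatic RNA accounts for the other differences cannot be told apart from changes within MII spermatocytes, also for the X-linked list.

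Spermatids of the wild type carried the highest levels of spermatid transcripts. Tnp1, the transition protein that replaces histones, stood at 134 ± 26 FPKM in MII spermatocytes and 2946 ± 501 in spermatids, and all 15 elongating spermatid markers (median 3.76) and all 21 round spermatid markers (median 3.42) rose. Lists that had fallen from MI to MII spermatocytes rose again, with flagellum genes (28 of 28, median 3.15) and late spermatocyte markers (14 of 15, median 3.19). Meiotic prophase markers (15 of 22, median 1.62) and piRNA pathway genes (12 of 20, median 1.69) did so as well. Insl3 stood at 690 ± 322 FPKM in MII spermatocytes and 18.8 ± 21.1 in spermatids. Somatic RNA in the MII fraction may thus contribute to the fall and the return of these lists. Its part cannot be told apart from changes within germ cells. Immediate early and stress genes fell (14 of 14, median −6.15), as did immune markers (12 of 13, median −4.27), Leydig cell markers (8 of 8, median −3.89) and X-linked housekeeping genes (20 of 24, median −1.82). In limma, 9673 genes differed, 5085 higher and 4588 lower. Camera passed 15 lists, 6 upwards and 9 downwards, with adjusted p from 0.299 to 0.429 with an estimated correlation and 19 lists called by fry. Quantile normalization moved the median change of all genes in the 3 successive comparisons from −0.07, 0.05 and 0.11 to −0.25, −0.21 and 0.20.

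**Figure D2:**
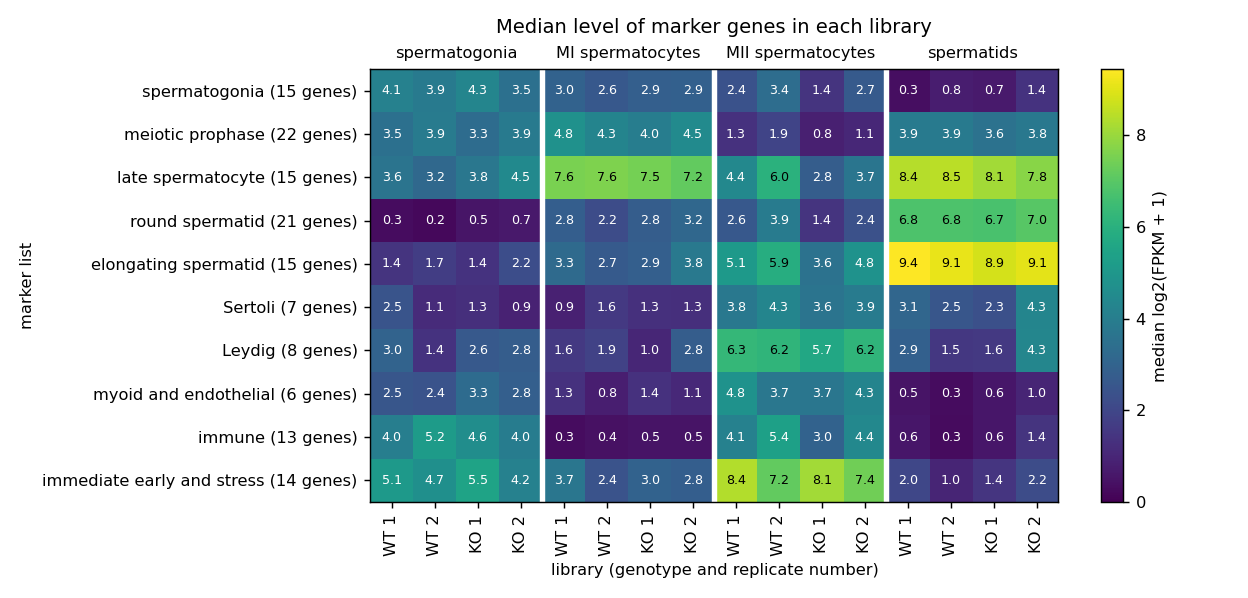
Median level, as log2(FPKM + 1), of 10 marker lists (rows) in each of the 16 libraries (columns, WT for wild type and KO for Tex10-deficient, with the replicate number). Leydig cell markers lie between 5.66 and 6.31 in the 4 MII libraries and at 4.34 in Tex10-deficient spermatid replicate 2, against at most 3.01 in the other libraries.

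In spermatogonia, 2 genes of T lymphocytes were higher in the Tex10-deficient libraries. Cd3g (XLOC_022574, chromosome 9, 44969572 to 44980431), a chain of the T cell receptor complex, rose from 3.40 ± 1.59 to 19.6 ± 2.8 FPKM. Ifng (XLOC_001810, chromosome 10, 118441046 to 118445892), the cytokine interferon gamma, rose from 0.813 ± 0.178 to 5.96 ± 1.71 FPKM. Their log2 changes were 2.27 (SE 0.28) and 1.92 (SE 0.24), each with a limma adjusted p = 0.010. Markers of macrophages and other immune cells had a median change of −0.32, spermatogonia markers −0.30, meiotic prophase markers −0.25 and sperm flagellum genes 0.41. Dmrt1 stood at 54.1 ± 4.5 and 40.2 ± 5.7 FPKM in wild-type and Tex10-deficient spermatogonia, Crabp1, a retinoid-binding protein, at 137 ± 46 and 58.2 ± 18.4, and Dmrtb1 at 17.4 ± 2.4 and 19.7 ± 5.5. None of these 3 markers was called (limma adjusted p = 0.98, 0.71 and 1). None of the 22 lists passed camera, the smallest adjusted p being 0.092 for the flagellum genes, and fry called 0. With a pseudocount of 0.1, with array weights and with either replicate block, 1 list passed camera. The list result also moved without wild-type replicate 1 or either Tex10-deficient replicate. Adjusted over the list alone, 1 immune, 1 Wnt target and 1 NF-kB target gene were lower, and over all genes 0.

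These 2 calls, 2 higher and 0 lower, stood beside 865 genes at an unadjusted p under 0.05, of which 504 were higher, where chance gives 655. Quantile normalization gave 15 higher and 8 lower. The count was 35 without wild-type replicate 1 and 0 without wild-type replicate 2 or either Tex10-deficient replicate, and it was 0 with a pseudocount of 0.1 and without the MII libraries. It was 4 without either wild-type MII library.

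In MI spermatocytes 22 genes changed, 7 higher and 15 lower. Among the rises, 3 named genes lie on the X chromosome. Prame (XLOC_023923, 135613002 to 135627705) rose from 0.658 ± 0.109 to 17.6 ± 4.5 FPKM, Slc10a3 (XLOC_023783, 74369217 to 74373349), a solute carrier, from 0.808 ± 1.027 to 10.3 ± 2.8, and Usp51 (XLOC_023475, 153006469 to 153009416), a deubiquitinase, from 0.570 ± 0.537 to 7.80 ± 2.68. Pmaip1 (XLOC_009922, chromosome 18), a pro-apoptotic protein and p53 target, rose from 1.54 ± 0.50 to 8.05 ± 1.70 FPKM. Apoc2 (XLOC_019506, chromosome 7, 19671579 to 19677941), an apolipoprotein that activates lipoprotein lipase, was listed at 0 in all 8 wild-type libraries. Its Tex10-deficient libraries held 6.41 and 3.83 FPKM in spermatogonia, 24.7 and 8.15 in MI spermatocytes, 0 and 2.06 in MII spermatocytes, and 7.47 and 5.19 in spermatids.

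Among the falls in MI spermatocytes, Chdh (XLOC_006103, chromosome 14, 30009023 to 30040527), the mitochondrial choline dehydrogenase, went from 59.6 ± 8.9 to 7.30 ± 0.66 FPKM, a log2 change of −2.86 (SE 0.37, limma adjusted p = 0.0051). Cnst (XLOC_000598, chromosome 1) fell from 34.7 ± 8.5 to 6.61 ± 0.42 FPKM, Zscan22 (XLOC_018381, chromosome 7), a zinc finger gene, from 33.0 ± 7.6 to 6.99 ± 0.70, and Rnf125 (XLOC_009727, chromosome 18), a ubiquitin ligase, from 42.4 ± 6.8 to 12.8 ± 0.5. Agtr1a (XLOC_005214, chromosome 13), an angiotensin II receptor, fell from 12.04 ± 1.18 to 2.05 ± 0.35 FPKM, and Pxdc1, Tmcc3, Sult6b1 and Syndig1l fell from between 6.15 and 8.70 to between 0.616 and 1.31. The adjusted p of these named rises and falls lay between 0.0051 and 0.035. The remaining 2 rises and 3 of the remaining falls carry predicted names, and the other 2 falls, Ankrd27 and Ppp3ca, named after their values were seen, were smaller than the 10 named by the rule. At most 1 gene was called without wild-type MI replicate 2 or without either Tex10-deficient MI library.

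Of the lists, 3 passed camera upwards in MI spermatocytes with the preset correlation only. They had adjusted p = 0.61, 0.998 and 0.998 with an estimated correlation, in the order below, and fry called 0. Genes of single copy on the Y chromosome had a median log2 change of 0.83, with 7 of 8 higher, and Uty stood at 1.04 ± 0.24 and 3.35 ± 0.06 FPKM and Zfy1 at 3.24 ± 0.81 and 8.64 ± 0.82. Elongating spermatid markers had a median of 0.42 with 13 of 15 higher, and Smcp, a protein of the sperm mitochondrial capsule, stood at 48.5 ± 5.1 and 119 ± 1 FPKM. X-linked housekeeping genes had a median of 0.28 with 17 of 24 higher, and Phf6 stood at 0.990 ± 0.534 and 3.26 ± 0.23 FPKM. Camera gave adjusted p = 3.8e-05, 0.00027 and 0.0016 for the 3 lists with the preset correlation. Over all genes 0 members of these lists were called, and adjusted over the list alone 4 Y-linked genes were called. The p53 target list, which holds Pmaip1, had a median of 0.08 and did not pass (adjusted p = 0.73).

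The MI count of 22 stood beside 765 genes at an unadjusted p under 0.05. It depended on single libraries, being 11 without wild-type replicate 1, 0 without wild-type replicate 2, 1 without either Tex10-deficient replicate and 47 without either wild-type MII library, while 67 (25 higher, 42 lower) were called without the MII libraries and 3 with a pseudocount of 0.1. It was 14 without either wild-type spermatid library. Quantile normalization gave 18 higher and 25 lower. Without Tex10-deficient MI replicate 2 the 3 lists no longer passed, with medians of 0.59 (adjusted p = 0.16), 0.32 (0.51) and 0.05 (0.55), and the X-linked list was also lost without wild-type MI replicate 2 (median 0.02, adjusted p = 0.58). The medians were larger without wild-type MI replicate 1 (elongating 0.72, X-linked 0.48) or Tex10-deficient MI replicate 1 (0.90 and 0.45), and the Y-linked median was 0.53 without wild-type MI replicate 2. Camera passed further lists without Tex10-deficient MI replicate 1, so the list result moved both ways.

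**Figure D3:**
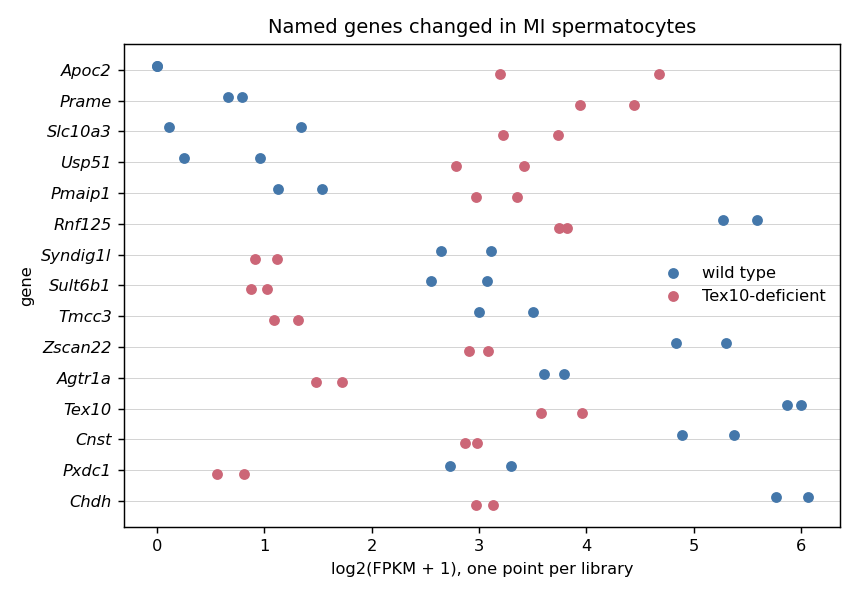
Level on the log2(FPKM + 1) scale of the 15 named genes called in MI spermatocytes, with 1 point per library and 2 libraries per genotype. The genotypes do not overlap for any of these genes, as the naming rule required.

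**Figure D4:**
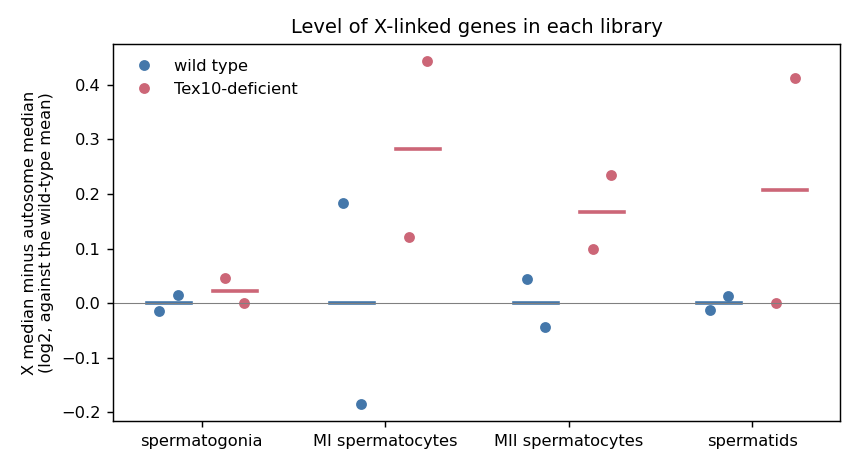
Median of X-linked genes minus median of autosomal genes in each library, on the log2 scale and relative to the wild-type mean of the same cell type, with points for libraries and lines for group means. In MI spermatocytes the wild-type libraries lie at 0.18 and −0.18 and the Tex10-deficient libraries at 0.12 and 0.44.

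In MII spermatocytes 1 gene fell in the Tex10-deficient libraries, and 6 lists of germ cell transcripts passed camera downwards with the preset correlation only. The lists below had adjusted p = 0.37 for the first 4, 0.38 for meiotic markers and 0.56 for elongating markers with an estimated correlation, and fry called 0 of the 22. Rxfp1 (XLOC_013798, chromosome 3, 79641611 to 79737880), a relaxin receptor, fell from 6.51 ± 0.23 to 0.265 ± 0.317 FPKM (log2 change −2.59, SE 0.26, limma adjusted p = 0.0014). All 28 sperm flagellum genes were lower (median −1.66), and Dnah8, a dynein heavy chain, stood at 74.99 ± 62.97 and 11.3 ± 7.2 FPKM. Late spermatocyte markers had a median of −1.42 with 15 of 15 lower, and Nek2, a mitotic and meiotic kinase, stood at 29.2 ± 22.5 and 3.46 ± 3.42 FPKM. Round spermatid markers had a median of −1.28 with 20 of 21 lower, piRNA pathway genes −0.90 with 20 of 20, meiotic prophase markers −0.71 with 21 of 22 and elongating spermatid markers −0.78 with 13 of 15.

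Among examples of these MII groups, Acrbp, an acrosomal protein, stood at 35.5 ± 26.2 FPKM in the wild type and 6.83 ± 0.42 in Tex10-deficient cells, the RNA helicase gene Ddx4 at 27.9 ± 21.5 and 7.39 ± 0.31, and Sycp3, of the synaptonemal complex, at 33.6 ± 19.4 and 8.62 ± 3.80. Camera adjusted p for flagellum, late spermatocyte, round spermatid, piRNA, meiotic and elongating lists were 7.4e-18, 4.4e-10, 3.2e-09, 3.2e-08, 6.2e-06 and 0.0085. With an estimated correlation none of the 6 passed. Adjusted over the list alone, 23 flagellum, 11 late spermatocyte, 11 round spermatid, 9 piRNA, 8 meiotic and 0 elongating genes fell, and over all genes 0 of each.

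Somatic markers in the same MII libraries went in different directions. Immune, X-linked and interferon lists passed camera with the preset correlation only, with adjusted p = 0.56, 0.65 and 0.38 with an estimated correlation. Immune markers had a median of −0.87 with 13 of 13 lower, and Lyz2, a macrophage lysozyme, stood at 101.6 ± 33.0 and 54.8 ± 16.5 FPKM. Leydig cell markers had a median of 0.24 and did not pass (adjusted p = 0.59), with Insl3 at 690 ± 322 and 767 ± 300 FPKM. X-linked housekeeping genes (median 0.30, 22 of 24 higher) and interferon response genes (median 0.40, 5 of 7 higher) passed upwards, and Ifit3, an interferon-induced gene, stood at 3.03 ± 1.06 and 6.88 ± 1.02 FPKM. Camera adjusted p were 0.0039, 0.0056 and 0.037 for the immune, X-linked and interferon lists with the preset correlation. Of these lists 0 genes were called over all genes, and adjusted over the list alone 1 interferon gene was called.

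Beside the 1 called gene in MII spermatocytes, 1738 had an unadjusted p under 0.05, 1379 of them lower. The fit pools the spread of all groups, and replicates differed most in MII spermatocytes, so these p may be too small. Median-of-ratios scaling gave 5 higher and 73 lower, and quantile normalization 41 higher and 149 lower. The count was 1253 (47 higher, 1206 lower) without wild-type replicate 1, 3 without wild-type replicate 2 or Tex10-deficient replicate 1, and 237 without Tex10-deficient replicate 2, and without either wild-type library Rxfp1 fell below the filter and was not tested. The medians of flagellum, late spermatocyte, round spermatid, piRNA and meiotic lists were −2.59, −2.24, −1.9997, −1.58 and −1.25 without wild-type replicate 1 and −0.70, −0.66, −0.57, −0.48 and −0.17 without wild-type replicate 2, and passed in both. Without Tex10-deficient replicate 2 the late spermatocyte, elongating and interferon medians were −2.17, −1.52 and 0.93, and without wild-type replicate 1 the immune median was −1.37. The immune list was lost without wild-type replicate 2 (median −0.36, adjusted p = 0.51) or Tex10-deficient replicate 1 (−0.43, 0.11), the X-linked list without wild-type replicate 2 (0.09, 0.32) or Tex10-deficient replicate 2 (0.05, 0.096), the elongating list without Tex10-deficient replicate 1 (median −0.13, adjusted p = 0.67), and the interferon list without wild-type replicate 1 (0.082), wild-type replicate 2 (0.061) or Tex10-deficient replicate 1 (0.16).

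No gene passed in spermatids, where the 5 smallest p belonged to 2 histone genes, Apoc2, Ndufa1 and Tex10. Hist1h2aa (XLOC_005189, chromosome 13), a testis histone gene, stood at 17.0 ± 4.7 FPKM in the wild type and 162 ± 99 in Tex10-deficient spermatids, and Hist1h1t (XLOC_005178, chromosome 13), the testis linker histone, at 5.93 ± 0.25 and 26.5 ± 10.8. Ndufa1 (XLOC_023627, X chromosome), a subunit of respiratory complex I, stood at 5.76 ± 0.20 and 0.646 ± 0.030 FPKM. The limma adjusted p of these 5 genes lay between 0.15 and 0.23. Reads of near-identical histone genes can be shared between copies, so values of single histone genes are uncertain. At an unadjusted p under 0.05 there were 284 genes, fewer than the 655 that chance gives. The fit takes 1 spread per gene over all groups. Median absolute differences between replicates (log2) were 0.262 and 0.374 in wild-type and Tex10-deficient spermatids, against 0.448 and 0.415 in MII spermatocytes. They were 0.297 and 0.345 in spermatogonia and 0.295 and 0.385 in MI spermatocytes, near the spermatid values. Those comparisons had 865 and 765 genes at an unadjusted p under 0.05. Unadjusted p may be too small in MII spermatocytes and too large in the other cell types, which limits a comparison of these counts with chance. Replicate spread alone does not account for the low count in spermatids. The count was 1 without either wild-type MI library, either wild-type spermatid library or Tex10-deficient spermatid replicate 1.

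In spermatids 5 marker lists passed camera upwards with the preset correlation only, and all 5 calls were lost without Tex10-deficient replicate 2. They had adjusted p = 0.85 for each with an estimated correlation, and fry called 0. Sertoli cell markers had a median of 0.74 with 7 of 7 higher, Leydig cell markers 0.75 with 8 of 8, immune markers 0.32 with 11 of 13, spermatogonia markers 0.27 with 13 of 15 and X-linked housekeeping genes 0.20 with 18 of 24. Insl3 held 33.8 and 3.89 FPKM in the wild-type and 6.14 and 108 in the Tex10-deficient spermatid libraries. Cd68, a macrophage marker, was listed at 0 in both wild-type spermatid libraries, and Wt1, of Sertoli cells, stood at 1.24 ± 0.59 and 4.57 ± 2.82 FPKM. Camera adjusted p were 0.00064, 0.017, 0.00064, 0.016 and 0.024 in this order with the preset correlation. Adjusted over the list alone, 1 Sertoli and 1 immune gene were called, and over all genes 0. Without Tex10-deficient replicate 2 the medians were −0.08, −0.51, 0.08, 0.00 and −0.09, and the 5 lists had adjusted p of 0.87, 0.19, 0.19, 0.82 and 0.93. Sertoli and Leydig lists were also lost without wild-type replicate 2 (medians 0.40 and 0.11, adjusted p = 0.10 and 0.98), and spermatogonia and X-linked lists without wild-type replicate 1 (medians 0.18 and 0.15, adjusted p = 0.11 and 0.35). Without Tex10-deficient replicate 1 the medians were 1.73, 2.27, 0.49, 0.70 and 0.32, and without wild-type replicate 1 the Leydig median was 1.33. The elongating spermatid list, with 10 of 15 members higher and a median of 0.13, had a mean of −0.28 and a downward test (adjusted p = 0.15).

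**Figure D5:**
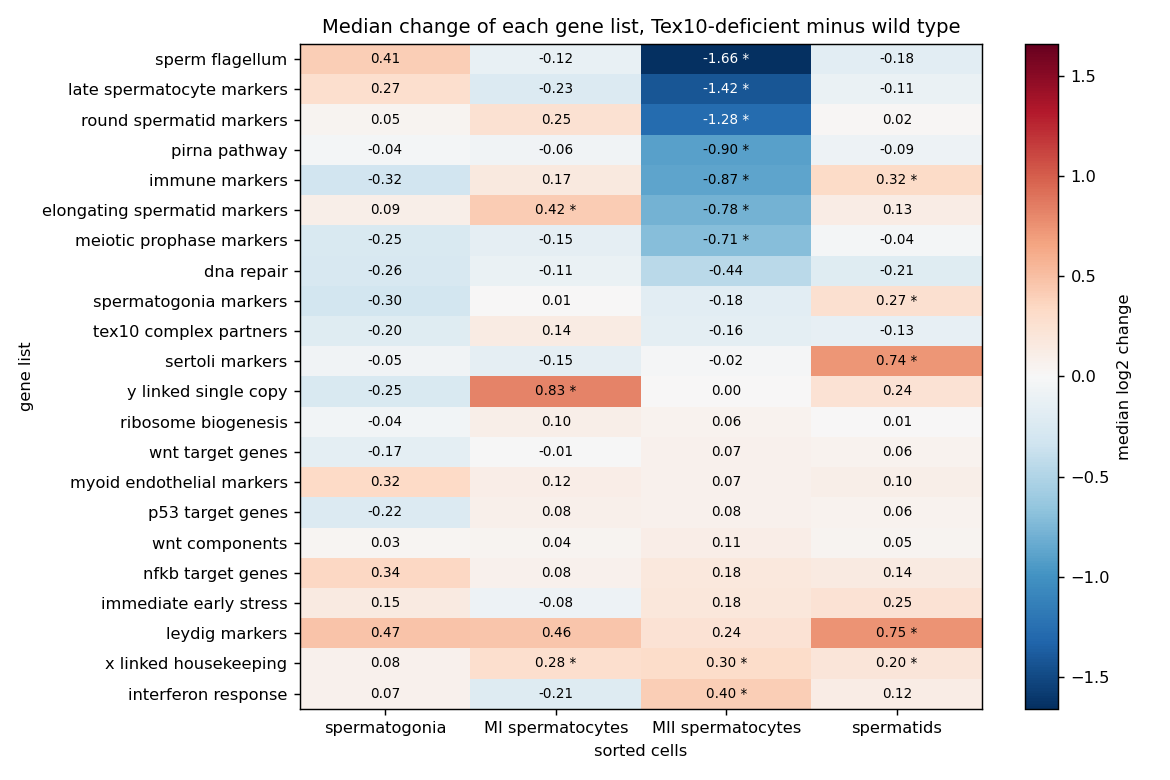
Median log2 change, Tex10-deficient minus wild type, of the 22 gene lists (rows) in the 4 sorted cell types (columns), with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Sperm flagellum genes range from 0.41 in spermatogonia to −1.66 in MII spermatocytes, and none of the asterisks held with an estimated correlation.

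Averaged over the 4 cell types, 13 genes changed, 5 higher and 8 lower. Beside Tex10 and Apoc2, Sfi1 (XLOC_003359, chromosome 11, 3131850 to 3193463), a centrosomal protein, rose from a mean of 1.13 to 4.12 FPKM and was higher in both Tex10-deficient libraries of each cell type. Hist1h1t rose from 49.7 to 90.4 FPKM (log2 change 1.37, SE 0.18, limma adjusted p = 0.0080), Prame from 4.85 to 12.7 and Ptn, a growth factor, from 1.45 to 5.05. Rxfp1 fell from 1.85 to 0.0875 FPKM, Agtr1a from 12.9 to 7.02 and Zfp748 (XLOC_005850, chromosome 13, 67538641 to 67553830), a zinc finger gene, from 19.1 to 5.16. The other 4 called genes, 9430065F17Rik, 1700012D01Rik, 1700065L07Rik and 4930511A02Rik, were lower and have predicted names. Copies similar to Sfi1 and zinc finger genes close in sequence to Zfp748 can share reads, so these values are uncertain. With a correlation allowed between same-numbered libraries of a genotype, a fit chosen after seeing the data, 4 of the 13 genes passed, Tex10, Apoc2 and Sfi1 among them, and Hist1h1t did not (adjusted p = 0.075). Without that correlation, Tex10, Apoc2, Sfi1 and Hist1h1t were called in all 16 fits that left out 1 library, whereas Ptn was called in 1 (without wild-type MII replicate 1), Agtr1a in 3 (without wild-type MII replicate 1, Tex10-deficient MII replicate 2 or spermatid replicate 1) and Prame in 3 (without wild-type MII replicate 1 or 2, or Tex10-deficient MII replicate 1). Zfp748 was lost in 10 of 16 such fits, with adjusted p up to 0.12, and Rxfp1 in 7 of the 14 in which it was tested, with adjusted p up to 0.074.

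Of the lists averaged over cell types, flagellum genes had a median of −0.38 (27 of 28 lower), late spermatocyte markers −0.43, piRNA genes −0.27, meiotic markers −0.24 and DNA repair genes −0.18. X-linked housekeeping genes had a median of 0.20 (22 of 24 higher) and Leydig cell markers 0.49 (7 of 8 higher). Camera adjusted p were 2.8e-05, 0.0012, 0.0018, 0.0046, 0.030, 9.5e-05 and 0.038 in this order, against adjusted p = 0.67 for each with an estimated correlation, and fry called 0. Adjusted over the list alone, 1 meiotic, 1 piRNA and 1 X-linked gene were called, and over all genes 0. Without the MII libraries the flagellum median was 0.04 (adjusted p = 0.84), the late spermatocyte, piRNA, meiotic and DNA repair lists no longer passed, and the X-linked (0.16, adjusted p = 0.0090) and Leydig (0.57, adjusted p = 0.0497) lists did.

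Lists of Tex10 complex partners (median −0.09), ribosome biogenesis (0.01), Wnt target genes (0.02), Wnt components (0.04), NF-kB target genes (0.16), p53 target genes (−0.01), myoid and endothelial markers (0.17) and immediate early genes (0.20) did not pass camera on average, nor in any single cell type. At an unadjusted p under 0.05, 1437 genes differed on average. Quantile normalization gave 4 higher and 4 lower genes. The count of 13 became 512 (36 higher, 476 lower) without wild-type MII replicate 1. It fell to between 5 and 8 without wild-type spermatogonia replicate 2, MI replicates 1 and 2, or spermatid replicates 1 and 2, and without Tex10-deficient spermatogonia replicate 2, MI replicates 1 and 2, MII replicate 1, or spermatid replicate 2. Without wild-type MII replicate 2 the late spermatocyte, piRNA and meiotic lists no longer passed (adjusted p = 0.073, 0.076 and 0.076). The DNA repair list was lost without replicate 2 of wild-type spermatogonia, MII spermatocytes or spermatids, replicate 1 of Tex10-deficient spermatogonia, MI or MII spermatocytes, or Tex10-deficient spermatid replicate 2, with medians from −0.17 to −0.12. The Leydig list was lost without wild-type MI replicate 1, replicate 2 of wild-type spermatogonia, MII spermatocytes or spermatids, replicate 2 of any Tex10-deficient cell type, or Tex10-deficient MII replicate 1, with medians from 0.17 to 0.56, and its median was 0.79 without Tex10-deficient spermatid replicate 1. Without wild-type MII replicate 1 the flagellum, late spermatocyte, piRNA and DNA repair medians were −0.59, −0.66, −0.49 and −0.28, the flagellum median was −0.17 without wild-type MII replicate 2, and the X-linked median was 0.13 without wild-type MI replicate 2 or Tex10-deficient spermatid replicate 2.

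Whether the effect of genotype differed between cell types was tested with an F test in limma. No gene passed, with 850 at an unadjusted p under 0.05 and a smallest adjusted p of 0.165. The smallest p belonged to Rxfp1, whose log2 change was −2.59 in MII spermatocytes and between −0.57 and −0.17 in the other cell types, to Rnf125 (1.11 in spermatogonia, −1.65 in MI spermatocytes) and to Ndufa1 (1.41 in MII spermatocytes, −2.04 in spermatids). Cd3g, Ifng and Prame came next, each with the same adjusted p. Calls in 1 cell type and not in another are therefore not shown to differ. Without wild-type MII replicate 1 the count was 255, and without Tex10-deficient MII replicate 1 it was 1.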

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

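The tests of each list in a cell type against the other 3, and all tests of explanations below except the count over 100 splits, were chosen only after the result was seen. Of 88 tests of a list's change in 1 cell type against its mean change in the other 3, 22 had an adjusted p under 0.05 with the preset correlation, and with an estimated correlation 0 did (adjusted p from 0.820 to 0.964). In spermatogonia the median difference was 0.80 for late spermatocyte markers, 0.47 for round spermatid markers, 1.05 for flagellum genes and −0.45 for Y-linked genes. In MI spermatocytes it was 0.40 for meiotic markers, 0.53 for round and 0.89 for elongating spermatid markers, 0.76 for Y-linked genes, 0.38 for flagellum genes and −0.42 for interferon response genes. In MII spermatocytes it was −0.60 for meiotic markers, −1.56 for late spermatocyte markers, −1.31 for round and −0.75 for elongating spermatid markers, −1.18 for immune markers, −0.82 for piRNA genes and −1.58 for flagellum genes. In spermatids it was 0.53 for spermatogonia markers, 0.45 for meiotic markers, 0.89 for Sertoli cell markers, 0.84 for immune markers and 0.27 for piRNA genes. The differences in spermatogonia, MI spermatocytes and spermatids contain the MII changes through the mean of the other cell types.

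Of 100 splits of the libraries into sets of 8 within cell types, drawn from 648, 1 gave as many as the 13 genes changed on average, the real one, and the highest other gave 4. This excludes chance as the source of the count only if libraries of different cell types are independent, and same-numbered wild-type libraries deviated together (r from 0.14 to 0.36). With same-numbered libraries of a genotype kept together there are 3 splits, too few for a share under 0.05, of which 1, the real one, gave 13 genes and the highest other 2. With a correlation allowed between those libraries, 4 of the 13 genes passed and Hist1h1t did not (adjusted p = 0.075).

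Of the 7 genes called higher in Tex10-deficient MI spermatocytes, 4 lie on the X chromosome, as do 3.85% of tested genes, and 0 of the 15 called lower do (Fisher exact p = 6.9e-05, two-sided, genes not being independent), but this p rests on calls of which 0 were left without wild-type MI replicate 2 and 1 higher gene without either Tex10-deficient MI replicate or with a pseudocount of 0.1. RNA carried over from spermatids is argued against as the whole source, because X-linked genes high in spermatids implied a larger share than autosomal ones in all 4 pairs of a Tex10-deficient and a wild-type library, by at least 2.64 percentage points, and the called genes needed at least 28.6%, although autosomal genes implied 3.02% and 3.19% in Tex10-deficient replicate 2, where elongating spermatid markers had a median level of 3.81 (2.86 in replicate 1, 3.27 and 2.68 in the wild type, log2). RNA of spermatogonia is argued against for the 4 called genes, which needed at least 228%, but for the X chromosome as a whole it cannot be told apart from other sources, since the X-linked share minus the autosomal one ran from −0.717 to 6.83 points over the 4 pairs, and the spread between libraries stays open too, the lowest Tex10-deficient library lying below the highest wild-type library (difference −0.0635, log2). The shift of X-linked against autosomal genes was 0.28 in MI spermatocytes, 0.02 in spermatogonia (gap −0.01), 0.17 in MII spermatocytes (gap 0.06, both Tex10-deficient libraries above both wild-type ones) and 0.21 in spermatids (gap −0.01), where it came from Tex10-deficient replicate 2 (0.41, against 0.00057 in replicate 1), the library with the high Leydig markers. In MII spermatocytes a different mix of cells cannot be told apart from a shift of the X chromosome. Flagellum genes were lower there (median −1.66), and wild-type MII libraries, rich in somatic markers, exceeded MI libraries in X-linked housekeeping genes (median 2.03). Incomplete silencing of some X-linked genes in meiosis may account for the single genes in MI spermatocytes, as a hypothesis found and tested on the same data. Wild-type levels of Prame, 4930595M18Rik, Slc10a3 and Usp51 were 0.0293, 0.289, 4.11 and 0.900 FPKM in spermatogonia. In wild-type spermatids they were 17.8, 37.8, 7.35 and 3.57 FPKM. Prame and 4930595M18Rik were thus barely detected in spermatogonia. In Tex10-deficient MI spermatocytes the 4 genes held 17.6, 17.3, 10.3 and 7.80 FPKM, each above its wild-type level in spermatogonia. For none of the 4 can the hypothesis thus rest only on a level kept from before meiosis.

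Germ cell lists were lower in Tex10-deficient MII libraries, while the wild-type libraries differed from each other. Wild-type MII replicate 1 had a Spearman rho of 0.914 and 0.946 with the Tex10-deficient MII libraries, above its 0.881 with wild-type replicate 2. Replicate 2 had 0.778 and 0.867 with the Tex10-deficient libraries. The wild-type MII libraries thus did not form a group apart from the Tex10-deficient ones. A different mix of cells in the sorted fraction cannot be told apart from a change within cells. Across 13099 genes the change correlated with the difference between the wild-type MII libraries (Pearson r = −0.57, and −0.02, −0.23 and −0.14 in spermatogonia, MI spermatocytes and spermatids), but both quantities use the same wild-type libraries, which can give such a correlation with no effect in common. A loss of germ cells alone, which would raise Leydig and immune markers alike, cannot be told apart from a change in the somatic cells as well, since the medians were 0.24 and −0.87, but the Leydig minus immune medians of single libraries (2.17 and 0.81 in the wild type, 2.69 and 1.76 in Tex10-deficient mice) overlapped, with a gap of −0.41. An effect of the genotype on the abundance of these transcripts within cells stays open and was not tested.

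Within 1 Mb on chromosome 13, 5 of 29 genes were lower on average at p under 0.01: 9430065F17Rik (log2 change −1.65), Zfp748 (−1.45), Rsl1 (−1.16), Zfp874a (−0.63) and Mterf3 (−0.61). Chance clustering of the 445 genes at p under 0.01 may account for their number in the window, since 883 of 1000 permutations of the genes over positions gave a window as unlikely. The permutations used p alone, so they do not weigh the shared direction or the size of the changes. Zfp748 (67538641 to 67553830) and 9430065F17Rik (67553035 to 67564010), both called on average, overlap in position and may not be separate calls. Reads shared between the zinc finger paralogs of this region were not tested, nor was a biological explanation.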

How the results depend on the processing

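The fits without the MII libraries, with robust eBayes, with a random replicate effect and of list tests with a library left out were chosen after seeing the data, and the cause of the differences below was not tested unless the setting's construction shows it. Of 910 values of called genes and Tex10 under the alternatives, 702 kept their direction and side of the threshold, 200 no longer passed, 8 newly passed and 0 reversed. Of 728 such values of called lists, 608 were kept, 107 no longer passed and 13 reversed. The fit with no filter tested 1 gene more, so it says nothing about stability. Depth is unknown, and 2 libraries per group limit the single comparisons. A group left with 1 library is assumed to vary like the others.

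Genes changed in spermatogonia (2) numbered 0 with a pseudocount of 0.1, 34 with 5, 1 with the filter of 5 FPKM, 23 with quantile normalization, 28 with array weights, 0 when grouped by the cell type field, 1 with only the 4 libraries and 0 without the MII libraries. Those in MI spermatocytes (22) numbered 3, 43, 43 (quantile), 52 (array weights), 3241 (cell type field), 6 (only 4 libraries) and 67 (without MII), the first 2 with the pseudocounts. Those in MII spermatocytes (1) numbered 5 and 21 with the pseudocounts, 78 with median-of-ratios scaling, 190 with quantile normalization, 4899 by the field and 0 with only 4 libraries. Spermatids (0) gave 3 and 1 with the pseudocounts. The average (13) gave 5 with a pseudocount of 0.1, 8 with quantile normalization and 0 by the field. By the field, whose groups mix titles of different cell types, the successive wild-type comparisons gave 3008 (MI, 6800) and 3480 (MII, 7489), and the F test 5138, while a pseudocount of 5 gave 5 in the F test.

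Leaving out 1 library at a time gave from 0 to 35 genes in spermatogonia, 0 to 47 in MI spermatocytes, 1 to 1253 in MII spermatocytes, 0 to 1 in spermatids, 5 to 512 on average and 0 to 255 in the F test. In the wild type the ranges were 4710 to 6987, 5532 to 7557 and 8597 to 9698. Tex10 log2 changes lay between −1.88 and −1.43, −2.36 and −1.98, −1.71 and −0.77, and −1.77 and −1.54 in the 4 cell types, and between −1.80 and −1.56 on average.

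Lists whose median turned in MII spermatocytes under the cell type field were meiotic (1.79), late spermatocyte (2.77), round (1.91) and elongating (0.996) spermatid, X-linked (−1.86), piRNA (2.36), flagellum (2.72) and interferon (−2.87). Without Tex10-deficient spermatid replicate 2 the spermatid medians of Sertoli (−0.084), Leydig (−0.51) and X-linked (−0.092) lists turned, and without replicate 1 they were 1.73, 2.27 and 0.324. Without the MII libraries the average of flagellum genes (0.038) turned, as did the camera direction for late spermatocyte markers (median −0.11).

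Whether replicate numbers pair the genotypes stays open, since the labels do not say so. Between genotypes, the deviations of same-numbered libraries correlated with r = 0.20, 0.0038, 0.31 and −0.13 in the 4 cell types. Within the wild type, same-numbered libraries of different cell types deviated together (r from 0.14 to 0.36), and within Tex10-deficient mice r ran from −0.08 to 0.42. With the replicate number as a block shared by both genotypes, 268 genes were called in MII spermatocytes, 1 in spermatids and 20 on average. With the block within genotype the counts were 39 in MI spermatocytes, 318 in MII spermatocytes, 2 in spermatids and 49 on average, with all 22, 1 and 13 genes of the MI, MII and average comparisons among them. Both blocks take spread shared by same-numbered libraries out of the error, so these counts show no stronger effect. With the block within genotype as a random effect (correlation 0.16), which keeps that spread in the error, 4 of the 13 genes on average passed, Tex10, Apoc2 and Sfi1 among them, while Hist1h1t had adjusted p = 0.075, and the MI count was 23. The F test called 0 genes under each block, and the 3 successive wild-type counts changed by less than 1.5 times. Camera called 7 lists on average and 3 in MI spermatocytes under both fixed blocks, and lost the interferon list in MII spermatocytes (adjusted p = 0.052 and 0.058).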

Other observations

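The test of the flank of Tex10 was chosen only after the result was seen, while the prediction for T cell genes was written before their values were seen, after Cd3g and Ifng had been called, and the genes of the next paragraphs were chosen after their values were seen.

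Transcripts of 5 genes encoding transition proteins and protamines, chosen after their values were seen, had lower estimates in Tex10-deficient spermatids, and none passed. Tnp1 stood at 2946 ± 501 FPKM in the wild type and 1199 ± 15 in Tex10-deficient spermatids (log2 change −1.29, SE 0.31, limma adjusted p = 0.71). Prm2, a protamine, stood at 2682 ± 1261 and 1061 ± 93 FPKM (log2 change −1.25), Prm1 changed by −1.25, Tnp2 by −1.41 and Prm3 by −1.65, each with an adjusted p of 1. The fixed list of 15 elongating spermatid markers, which holds these genes, had a median of 0.13 in spermatids with 10 members higher.

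The testis linker histone Hist1h1t was higher in all 4 cell types, with log2 changes of 1.89 in spermatogonia, 0.62 in MI spermatocytes, 1.05 in MII spermatocytes and 1.93 in spermatids. Hist1h2aa went both ways, from 10932 to 4641 FPKM in spermatogonia and from 17.0 to 162 in spermatids, and Hist1h2ba stood at 63.9 and 179 FPKM in spermatogonia and was listed at 0 in both wild-type spermatid libraries. H2afx, the histone variant of DNA damage signalling, changed by 0.59 on average (limma adjusted p = 0.49). Values of single histone genes are uncertain because reads can be shared between copies.

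More T lymphocyte RNA in the Tex10-deficient spermatogonia libraries is a hypothesis for the rise of Cd3g and Ifng. Of 30 other T cell genes 11 were tested, and their median log2 change in spermatogonia was 1.24, with 10 higher (camera p = 5.3e-13 with the preset correlation and p = 0.0059 with an estimated correlation). In 8 of the 11, both Tex10-deficient libraries lay above both wild-type libraries. Icos held 9.90 and 1.75 FPKM in the wild-type and 21.5 and 16.8 in the Tex10-deficient libraries, and Il2rb, the most abundant, 25.5 and 6.92 against 48.8 and 22.5. Medians in the other cell types were 0.08, 0.06 and −0.02. The values are consistent with more lymphocytes among the sorted cells, whether from the sort or from the testis, and how the cells were gated is not given in the sources used here.

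DNA of another strain carried along with the engineered allele could change genes near Tex10. Within 5 Mb on chromosome 4, 3 of 71 genes had p under 0.01 on average, Clta (log2 change 0.78), Anp32b (0.49) and Ppp3r2 (−0.69), against 445 of 12592 genes with a position (Fisher exact p = 0.74, two-sided). With so few genes, this cannot be told apart from chance.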
